A study of Homo sapiens with 6 samples.

How the data were processed

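Gene expression was measured in MCF7, an established estrogen receptor-positive line of human breast adenocarcinoma. Per the labels' protocols, the cells were kept without serum for 24 h and then treated for 24 h with 9 µM GW4064, a synthetic agonist of the bile acid receptor FXR (gene NR1H4), or with vehicle, 0.3% DMSO. The sample titles call the control cells untreated, while the protocol and the design text describe vehicle, and they are called vehicle here. The submitters' design text states 3 biological replicates in each group and gives the dose as the IC50 in these cells. Total RNA was extracted with a column kit and labelled with biotin by a 3' IVT kit, per the labels.

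The deposited table holds log2 values, 1 per probe set and array, which the authors made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of each probe set. The notes also name the affy package, and versions are not given in the sources used here. The values ran from 1.62 to 14.1, and the medians of the 6 arrays lay between 5.21 and 5.26. Because of this normalization, a shift of all transcripts in 1 direction would not be visible, and each difference is relative to the rest of the array. Values near the bottom of the scale hold mostly background, so that the fold of a dim gene is understated, and values near the top can be compressed. Probe-level files were not analysed here, nor were scan dates or batches, so that a batch that follows the groups could not be examined. No column of the table was left unused.

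Probe sets were named through the platform annotation supplied with the table, and symbols were updated through Entrez identifiers to the RefSeq annotation of GRCh38.p14. That annotation was used for names only, since no build is named for the array values. Of 54675 probe sets, 62 were the manufacturer's controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Identifiers of 41037 probe sets matched RefSeq. A probe set with several symbols was never used to name a gene. For each gene the probe set with the highest mean log2 value over all 6 arrays was taken, without regard to the groups, which gave 19775 genes. No filter on dim genes was applied.

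The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, intercept and treatment, 4 residual degrees of freedom). P-values were two-sided and were adjusted by the method of Benjamini and Hochberg over the 19775 genes, with a threshold of 0.05. They rest on the spread between replicates that the design text calls biological. A difference is the mean log2 value of the GW4064 arrays minus that of the vehicle arrays. The ± gives its standard error from limma unless SD or bootstrap SE is written. Folds are 2 raised to the size of that difference.

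The main tests, 34 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The lists held 667 distinct genes, of which 606 were measured. Each list was compared with all other genes by camera in limma, with the preset inter-gene correlation of 0.01, and p-values were adjusted over the 34 lists. The test was repeated with a correlation estimated for each list and with fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. The rule named 14 genes with the largest rises and 14 with the largest falls, among those past the threshold whose ranges in the groups did not overlap. It also named up to 4 members of each list that passed the test, by size of difference. A fixed set of FXR and estrogen receptor genes and the reference genes were named whether or not they passed. Genes outside this rule are named where a count was 5 or less and in the gene groups under the other observations, and these names were chosen after their values were seen.

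The procedure was tested on simulated arrays of the 19775 genes with the means and spreads of the real ones. Of the changed genes, 55 of 80 with a log2 difference of 0.5, 79 of 80 with 1 and 40 of 40 with 2 were recovered, none with the wrong sign. Of 19575 unchanged genes 8 were called. Of the simulated lists, 2 of 2 shifted by 0.5 and 0 of 32 others were called. The simulated genes varied independently, and no genes outside the 2 shifted lists were changed in that run. It therefore does not test camera on lists whose genes vary together, or where many other genes change. The number of arrays, 3 per group, limits the precision of each value.

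The alternatives were a replicate block, leaving out each array, 2 filters on dim genes, 3 treatments of a gene's probe sets, 2 further normalizations, another variance model and array weights. The probe sets were averaged per gene, limited to those designed for 1 gene, or tested singly. RNA quality was taken as the 3' minus 5' difference in log2 value of the control probe sets for ACTB and GAPDH, and the groups were compared by an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.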

Results

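The expression of 19775 genes was measured on 6 arrays, 3 of MCF7 cells treated with the FXR agonist GW4064 at 9 µM for 24 h and 3 of cells given vehicle. The series asks how the transcriptome of these breast cancer cells responds to activation of NR1H4. Values of arrays within a group correlated across genes with r between 0.992 and 0.998, and those of arrays of different groups with r between 0.972 and 0.981. The first principal component held 82.3% of the variance and separated the groups. The second held 10.1% and spread vehicle replicates 2 and 3.

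GW4064 changed the expression of a large part of the measured genes. In limma's test 3438 genes were higher and 4180 were lower with GW4064 (adjusted p under 0.05), together 38.5% of the genes. Among them were 539 genes at least 2-fold higher with GW4064 and 937 genes at least 2-fold lower with GW4064. The larger number of falls depended on the probe sets. Averaged over a gene's probe sets, 3528 genes were higher and 3554 lower, with 440 and 437 at least 2-fold. With probe sets designed for 1 gene, 443 were at least 2-fold higher and 879 at least 2-fold lower. The median difference over all genes was 0.0255. Of the 7618 genes past the threshold, 7543 had ranges in the groups that did not overlap.

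The 14 largest rises were in genes of varied function. CYP1A1, a xenobiotic monooxygenase, rose 9.89-fold, by 3.31 ± 0.09 on the log2 scale (n = 3 per group, limma adjusted p = 1.09e-06). The stress-inducible chaperone gene HSPA6 rose 8.58-fold (3.10 ± 0.13) and the chaperone gene HSPA4L 7.98-fold (3.00 ± 0.10). ANXA1, a phospholipid-binding annexin, rose 7.85-fold (2.97 ± 0.08), and RND1, a Rho-family GTPase, 7.35-fold (2.88 ± 0.09). LTB, a cytokine of the tumour necrosis factor family, rose 6.71-fold (2.75 ± 0.09). TAF1A, a subunit of an RNA polymerase I factor, rose by 2.66 ± 0.16, the arginase gene ARG2 by 2.53 ± 0.16 and PSAT1, a serine synthesis enzyme, by 2.47 ± 0.10. BEX5 rose by 2.44 ± 0.14, GPCPD1, a glycerophosphocholine phosphodiesterase, by 2.42 ± 0.11 and the epsilon tubulin gene TUBE1 by 2.39 ± 0.08. Adjusted p in limma was at most 1.09e-05 for these genes.

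The largest rise in the table belonged to a probe set of PDCD4, an inhibitor of translation, which went from 3.29 to 7.41 (4.12 ± 0.09, 17.4-fold, limma adjusted p = 3.08e-07). It was not shared by brighter probe sets of the same gene, which were looked at after its value was seen. Another 4, which the annotation pairs with both PDCD4 and MIR4680 and which were therefore not used for naming, had means from 7.56 to 10.3 and differences from -1.72 to -0.05. The direction of PDCD4 is thus unsettled in these data. NBPF20, a member of a family of near-identical copies, rose 5.64-fold (SE of the log2 difference 0.15), while 3 probe sets shared with its relatives had differences from -0.30 to -0.17. With the probe sets of a gene averaged, the rises of ANXA1, LTB, ARG2 and TUBE1 became 1.597, 1.57, 1.48 and 1.33. With only probe sets designed for 1 gene, LTB rose by 0.38 and ARG2 had a difference of 0.43, which did not pass (limma adjusted p = 0.0579).

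The 14 largest falls were in genes of varied function. IFIT1, an interferon-induced inhibitor of viral translation, fell 8.64-fold (-3.11 ± 0.24, limma adjusted p = 2.71e-05). The adenylyl cyclase gene ADCY1 fell by 3.05 ± 0.19, the interferon-responsive SAMD9 by 3.03 ± 0.32 and the metalloproteinase gene MMP16 by 3.00 ± 0.17. The chemokine gene CXCL14 fell by 2.77 ± 0.16, and BCL2, which opposes apoptosis, fell 6.77-fold (-2.76 ± 0.10, limma adjusted p = 1.91e-06). CMPK2, a mitochondrial nucleotide kinase gene, fell by 2.75 ± 0.28, and PIK3R3, a regulatory subunit of PI3-kinase, by 2.73 ± 0.08. UGT2B15, which conjugates steroids, fell by 2.69 ± 0.23, LOC441179 by 2.67 ± 0.16 and TMEM164 by 2.63 ± 0.09. The noncoding RNA gene RMST fell by 2.62 ± 0.15 and the sulfate transporter gene SLC26A2 by 2.59 ± 0.10. The histone gene H2BC4 fell by 2.64 ± 0.11 on its own probe set, while 3 probe sets shared with near-identical histone genes had differences from -0.94 to 0.12. Adjusted p in limma was at most 0.00013 for the 14 falls.

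Several of these falls were smaller on other probe sets, or were not shared by them. The fall was shared by 2 of 4 probe sets of BCL2, 3 of 5 of MMP16, 4 of 5 of ADCY1 and 2 of 3 of RMST. On average over its probe sets ADCY1 fell by 1.35, SAMD9 by 1.96, MMP16 by 0.72, BCL2 by 0.73 and RMST by 0.91. With probe sets designed for 1 gene, the differences of CXCL14 (-0.42, limma adjusted p = 0.0529) and UGT2B15 (-0.02, adjusted p = 0.884) did not pass.

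**Figure D1:**
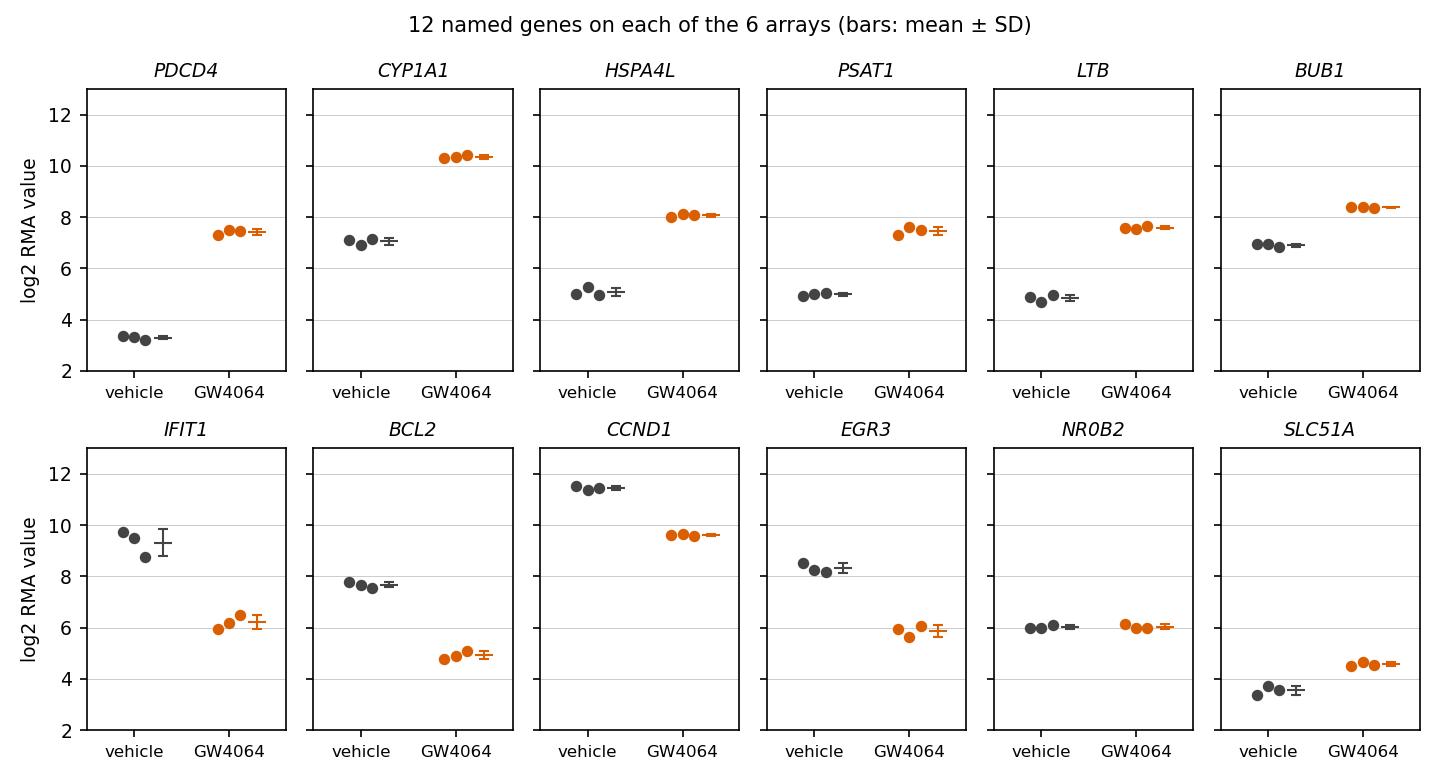
Log2 RMA values (vertical axis) of 12 named genes on each of the 3 vehicle and 3 GW4064 arrays (horizontal axis), with the mean ± SD beside the points. The groups do not overlap for 11 genes, with the largest gap for the probe set of PDCD4 (3.29 against 7.41), while NR0B2 lies at 6.03 and 6.04.

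Most known targets of FXR did not pass limma's test, and 14 of the 26 FXR-induced genes had a mean log2 value under 5, where a response can be masked by background. NR0B2, the repressor that FXR induces in liver, had a difference of 0.02 ± 0.08 (limma adjusted p = 0.903) at a mean of 6.03 in vehicle. The bile acid transporter genes SLC51B (0.10 ± 0.11, adjusted p = 0.532, 3.98 in vehicle) and ABCB11 (0.20 ± 0.11, adjusted p = 0.195, 4.98 in vehicle) and the hormone gene FGF19 (-0.03 ± 0.09, adjusted p = 0.84, 4.51 in vehicle) did not pass limma's test either. With array weights SLC51B (0.20, adjusted p = 0.017) and ABCB11 (0.33, adjusted p = 0.000767) passed it. Those weights put 54.96 on vehicle replicate 1, so that both calls rest mainly on 1 vehicle array. Without 1 array at a time neither passed, with differences from 0.03 to 0.205 for SLC51B and from 0.132 to 0.29 for ABCB11. SLC51A, which encodes the partner subunit of SLC51B, rose 2.04-fold (1.03 ± 0.11, adjusted p = 0.00011), also at a dim level, 3.55 in vehicle and 4.58 with GW4064. Of 26 FXR-induced genes 5 rose (FABP6, FGG, PDK4, SLC27A5 and SLC51A), 2 fell (PPARA and VLDLR) and 19 did not pass, with the same counts adjusted over the list alone. PPARA, a receptor for fatty acids, fell by 1.00 ± 0.08, the lipoprotein receptor gene VLDLR fell by 0.90 ± 0.11, and SLC27A5 rose by 0.63 ± 0.11. The list had a median of 0.03 and was not called by camera (adjusted p = 0.762), and of the 12 members with a mean of at least 5, 2 rose and 2 fell (median -0.00445).

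None of the 7 measured FXR-repressed genes passed the test over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.74), among them the aromatase gene CYP19A1 (0.01 ± 0.08, limma adjusted p = 0.918, 3.94 in vehicle). Their mean was 4.08 in vehicle, so near the bottom of the scale that a fall would hardly show. RXRA, the dimer partner of FXR, fell 3.63-fold on its brighter probe set (-1.86 ± 0.08, limma adjusted p = 2.21e-06) and by 0.29 averaged over its 2 probe sets, which went opposite ways. NR1H4 itself was not analysed here, since no probe set carried its name alone. Averaged over probe sets, PPARA had a difference of -0.14 (limma adjusted p = 0.266) and SLC27A5 rose by 0.31, while SLC27A5 had -0.01 (adjusted p = 0.959) on the probe set designed for 1 gene.

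Genes that estrogen induces fell together. Of 32 measured, 22 fell, 2 rose (FKBP4 and RERG) and 8 did not pass, and adjusted over the list alone 23 fell and 2 rose. The median was -0.85 and camera called the list lower (adjusted p = 1.71e-08), though not with an estimated correlation (adjusted p = 0.0801). The transcription factor gene EGR3 fell by 2.45 ± 0.14, the secreted glycoprotein gene STC2 by 2.23 ± 0.13, AGR3 by 1.89 ± 0.08 and CCND1, which encodes cyclin D1, by 1.84 ± 0.08. The progesterone receptor gene PGR fell 3.02-fold (-1.59 ± 0.27, limma adjusted p = 0.00152) and the estrogen receptor cofactor gene GREB1 3.33-fold (-1.74 ± 0.10, adjusted p = 7.25e-06). TFF1, a classical estrogen target, had a difference of -0.01 ± 0.07 (limma adjusted p = 0.932) at 13.5, near the top of the scale, where a change can be compressed. STC2 and CCND1 fell by 1.40 and 1.12 averaged over probe sets, where the list median was -0.49.

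Markers of luminal epithelial identity were also lower. Of 15 measured, 10 fell, 1 rose (TBX3) and 4 did not pass (AGR2, ELF3, KRT18 and MLPH), with the same counts adjusted over the list alone. The median was -0.37 (camera adjusted p = 0.001, and adjusted p = 0.146 with an estimated correlation). The developmental factor gene TFAP2A fell by 1.27 ± 0.08, the estrogen receptor gene ESR1 by 1.21 ± 0.07 (2.32-fold), the prolactin receptor gene PRLR by 1.18 ± 0.15 and MYB by 0.83 ± 0.10. This result depended on the probe sets. For ESR1, 6 of 9 probe sets shared the direction of the brightest, and their average had a difference of -0.09 (limma adjusted p = 0.572). Averages left a fall of 0.55 for TFAP2A, reversed PRLR (0.55, limma adjusted p = 0.0163) and MYB (0.02, adjusted p = 0.887) and ended the list's call (median -0.18, camera adjusted p = 0.0592), while with probe sets designed for 1 gene the median was -0.80.

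Growth factor receptors and their early response genes fell as well. Of 19 receptor tyrosine kinases and ligands, 11 fell, 2 rose (TGFA and VEGFA) and 6 did not pass, with the same counts adjusted over the list alone. The median was -0.51 (camera adjusted p = 0.000784, and adjusted p = 0.264 with an estimated correlation). ERBB4 fell by 2.17 ± 0.08, FGFR4 by 1.56 ± 0.16, FGFR2 by 1.38 ± 0.08 and the insulin-like growth factor receptor gene IGF1R by 1.30 ± 0.08. ERBB2 fell by 0.96 ± 0.08 on its brightest probe set (limma adjusted p = 4.61e-05), which its other 2 did not share, and their average reversed (0.12, adjusted p = 0.259). Averages of FGFR2 did not pass (-0.19, limma adjusted p = 0.058), those of ERBB4, FGFR4 and IGF1R were -1.07, -0.62 and -0.38, and with probe sets designed for 1 gene FGFR2 had 0.09 (adjusted p = 0.585) and the list was not called (median -0.15, camera adjusted p = 0.0544). The list median was -0.21 with averages, -0.77 among members with a mean of at least 5 and -0.90 among those above the median level.

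Of 22 immediate early and MAPK feedback genes, 14 fell, 3 rose (ETV5, FOSL1 and PHLDA1) and 5 did not pass (DUSP5, ETV4, JUN, SPRED1 and SPRY4), and adjusted over the list alone 14 fell and 6 rose. The median was -0.60 (camera adjusted p = 0.00602, and adjusted p = 0.319 with an estimated correlation). Besides EGR3, the AP-1 subunit genes FOS and FOSB fell by 2.32 ± 0.18 and 2.11 ± 0.23 and the growth-responsive factor gene EGR1 by 1.93 ± 0.09. With averaged probe sets the list median was -0.39.

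Targets of ATF4, the transcription factor of the integrated stress response, rose together. Of 35 measured, 28 rose, 2 fell (STC2 and ATF5) and 5 did not pass (ALDH1L2, ATF4, DDIT4, FGF21 and PSPH), with the same counts adjusted over the list alone. The median was 0.87 and camera called the list higher (adjusted p = 6.27e-13), though not with an estimated correlation (adjusted p = 0.146). Besides PSAT1, the amino acid transporter subunit gene SLC3A2 rose 4.66-fold (2.22 ± 0.08, limma adjusted p = 1.96e-06) and the serine synthesis gene PHGDH 4.59-fold (2.20 ± 0.07, adjusted p = 1.51e-06). A brighter probe set shared by PHGDH and the MZT2 genes had a difference of 0.15. STC2, which also belongs to the estrogen list, fell by 2.23 ± 0.13.

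Many heat shock genes and chaperone genes of the endoplasmic reticulum (ER) rose. Of 14 heat shock genes, 12 rose, none fell and 2 did not pass (DNAJB1 and HSPB1), and adjusted over the list alone 13 rose. The median was 0.49 (camera adjusted p = 2.23e-06, and adjusted p = 0.264 with an estimated correlation). Besides HSPA4L, the chaperone genes HSPH1, CHORDC1 and STIP1 rose by 2.12 ± 0.16, 1.73 ± 0.08 and 0.63 ± 0.09, and with probe sets designed for 1 gene HSPH1 and CHORDC1 rose by 1.17 and 0.61, while STIP1 averaged over probe sets rose by 0.98. Of 19 ER chaperone genes, 9 rose, 1 fell (SEL1L) and 9 did not pass, and adjusted over the list alone 10 rose and 1 fell. The median was 0.29 (camera adjusted p = 0.0111, and adjusted p = 0.66 with an estimated correlation). The ER cochaperone gene DNAJB9 rose by 1.28 ± 0.17, SDF2L1 by 0.84 ± 0.08, MANF by 0.79 ± 0.10 and HSP90B1 by 0.72 ± 0.12. This call was lost without vehicle replicate 3 (median 0.19, camera adjusted p = 0.059), the array with the lowest 5' control signal.

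Of 8 metallothionein list members, 6 rose, 1 fell (the zinc exporter gene SLC30A1) and 1 did not pass (MT1M), with the same counts adjusted over the list alone. The median was 0.89 (camera adjusted p = 0.0168, and adjusted p = 0.521 with an estimated correlation). MT1X rose by 1.35 ± 0.16, MT2A by 1.13 ± 0.14, MT1F by 1.07 ± 0.17 and MT1H by 1.04 ± 0.16. These genes are near-identical copies that share probes, so that single members are uncertain. The call was lost without vehicle replicate 3 (camera adjusted p = 0.0664) and with array weights (adjusted p = 0.0782), with medians of 0.95 and 0.92, and with probe sets designed for 1 gene 3 members were left with a median of -0.03 (adjusted p = 0.809).

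Other lists of stress and xenobiotic sensing moved less uniformly. Of 22 NRF2 targets, 9 rose, 3 fell (AKR1C1, AKR1C2 and AKR1C3) and 10 did not pass, and adjusted over the list alone 9 rose and 4 fell (median 0.07, camera adjusted p = 0.321). The cystine transporter gene SLC7A11 rose by 2.16 ± 0.10, PIR by 0.88 ± 0.13 and the malic enzyme gene ME1 by 0.92 ± 0.08, while the aldo-keto reductase gene AKR1C3 fell by 1.06 ± 0.08. Besides CYP1A1, of 9 AhR targets SLC7A5, CYP1B1 and NQO1 rose, TIPARP fell and 4 did not pass (AHRR, ALDH3A1, CYP1A2 and LRAT), which makes 4 rises and 1 fall, or 4 and 3 adjusted over the list alone. That list had a median of 0.14 (camera adjusted p = 0.567). The amino acid transporter gene SLC7A5 rose by 0.64 ± 0.11, CYP1B1 by 0.45 ± 0.11 (0.73 averaged over probe sets), and TIPARP fell by 0.52 ± 0.08. Of 12 PXR and CAR targets, 1 rose (ALAS1), 3 fell (CYP2C8, ABCB1 and ABCC1) and 8 did not pass, with the same counts adjusted over the list alone (median -0.07, camera adjusted p = 0.864). ALAS1, the first enzyme of heme synthesis, rose by 1.19 ± 0.10, and CYP2C8 fell by 1.07 ± 0.25 (0.56 averaged over probe sets). The falls of ABCB1 (-0.43 ± 0.10) and ABCC1 (-0.30 ± 0.10) were small, and that of ABCB1 did not pass averaged over probe sets (-0.18, limma adjusted p = 0.1). ABCC1 did not pass without vehicle replicate 1 or 3 (-0.30 and -0.23, adjusted p = 0.0959 and 0.0724) or GW4064 replicate 1 or 3 (-0.27 and -0.29, adjusted p = 0.117 and 0.112).

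**Figure D2:**
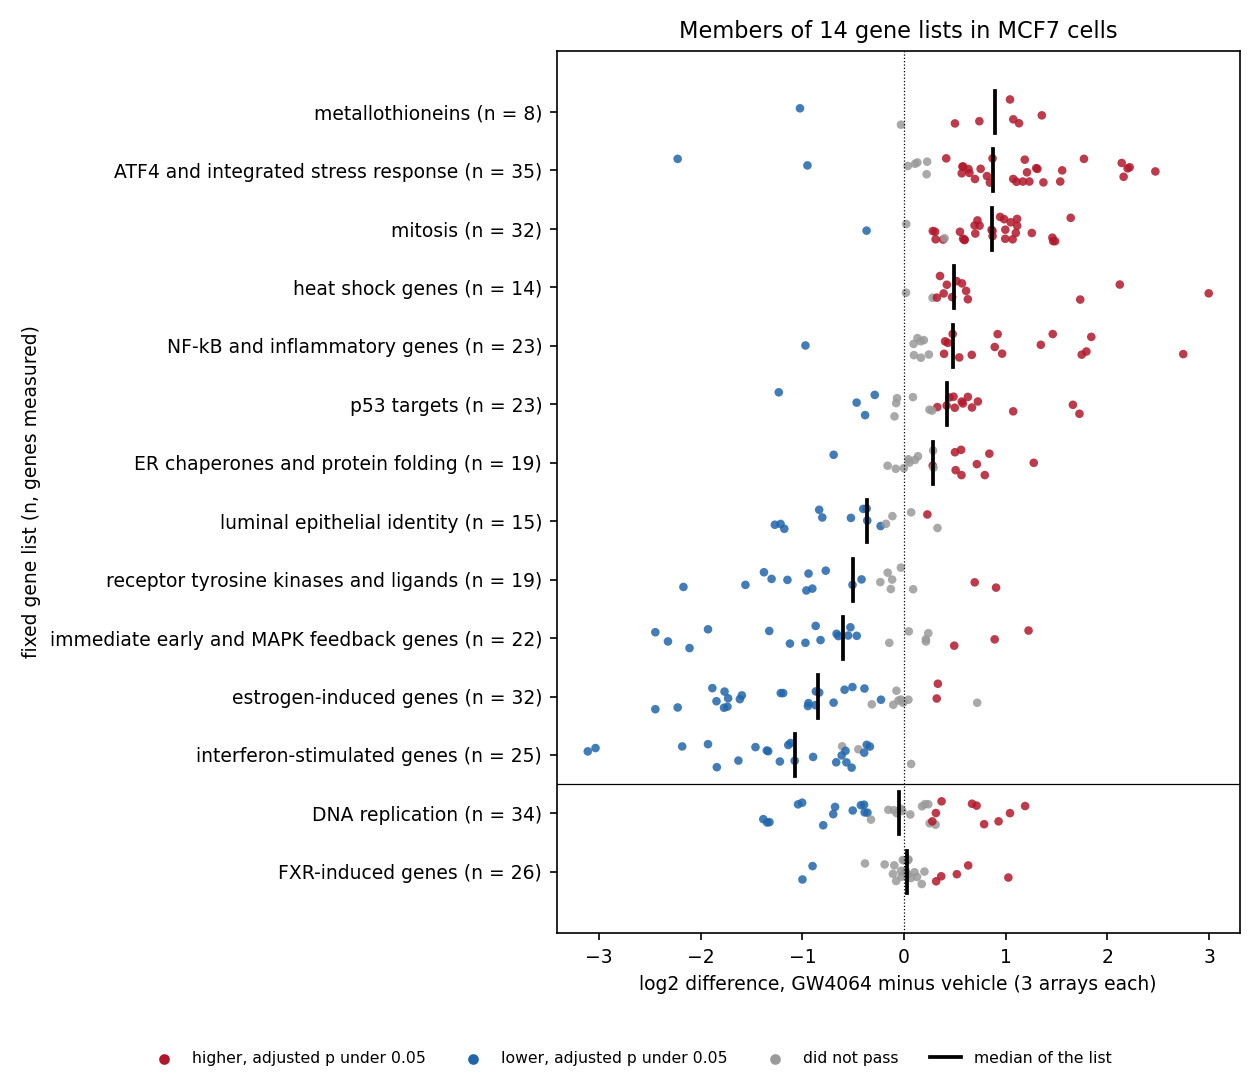
Log2 difference between GW4064 and vehicle (horizontal axis, 3 arrays per group) of each measured gene of 14 fixed lists (vertical axis, the 12 lists called by camera above the line), coloured by the result of limma's test. Black bars are medians, from -1.08 for interferon-stimulated genes to 0.89 for metallothioneins, and the DNA replication list holds both rises and falls around a median of -0.05.

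Genes of mitosis rose while those of DNA replication were divided. Of 32 mitotic genes, 29 rose, 1 fell (ASPM) and 2 did not pass (AURKA and KIF11), and adjusted over the list alone 30 rose and 1 fell. The median was 0.87 (camera adjusted p = 6.27e-13, and adjusted p = 0.146 with an estimated correlation). The mitotic kinase genes NEK2, BUB1, CDK1 and AURKB rose by 1.64 ± 0.07, 1.49 ± 0.07, 1.47 ± 0.08 and 1.46 ± 0.07, with limma adjusted p of at most 6.43e-06, and BUB1 by 0.77 averaged over probe sets. The proliferation marker gene MKI67 rose 1.83-fold (0.87 ± 0.09, limma adjusted p = 0.000112). Of 34 DNA replication genes, 9 rose, 13 fell and 12 did not pass, and adjusted over the list alone 9 rose and 14 fell (median -0.05, camera adjusted p = 0.567). The cyclin E2 gene CCNE2 fell by 1.38 ± 0.12, the sliding clamp gene PCNA by 1.35 ± 0.10 and the phosphatase gene CDC25A by 1.32 ± 0.09, while the primase gene PRIM1 rose by 1.19 ± 0.15. CCNE2 fell by 0.79 and CDC25A by 0.58 averaged over probe sets.

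Of 16 CDK inhibitors and G1 cyclins, 4 rose (CDKN1A, CDKN1C, CDKN2D and RB1), 5 fell (CCND1, CCNE1, CCNE2, CDK6 and MYC) and 7 did not pass, and adjusted over the list alone 5 rose and 7 fell. The median was 0.10, the mean -0.20 and the direction of camera lower, without a call (adjusted p = 0.921). CDKN1A, which encodes the CDK inhibitor p21, rose 1.34-fold (0.42 ± 0.08, limma adjusted p = 0.00365). CDKN2D rose by 1.49 ± 0.12 and CDK6 fell by 1.62 ± 0.28, but CDKN2D, at 0.86 averaged over probe sets, did not pass with probe sets designed for 1 gene (0.23, limma adjusted p = 0.254), nor CDK6 averaged over probe sets (-0.40, adjusted p = 0.0892).

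Targets of p53 rose in part. Of 23 measured, 13 rose, 4 fell (MDM2, RRM2B, TP53I3 and TP53INP1) and 6 did not pass, and adjusted over the list alone 14 rose and 4 fell. The median was 0.42 (camera adjusted p = 0.0168, and adjusted p = 0.543 with an estimated correlation). The stress sensor gene GADD45A rose by 1.73 ± 0.09, the death receptor gene FAS by 1.66 ± 0.24 and the cytokine gene GDF15 by 1.07 ± 0.08, while TP53INP1 fell by 1.23 ± 0.07. MDM2, the main feedback inhibitor of p53, was among those that fell. With probe sets designed for 1 gene the list was not called (median 0.30, camera adjusted p = 0.0609), FAS had a difference of 0.19 (limma adjusted p = 0.273) and GDF15 rose by 0.42, and averaged over probe sets FAS and GDF15 rose by 0.95 and 0.58 and TP53INP1 fell by 0.52. The list was not called either among genes above the median level (median 0.33, camera adjusted p = 0.0808).

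In the BCL2 family and caspases, 9 of 20 genes rose, 7 fell and 4 did not pass (BCL2A1, CASP8, DIABLO and XIAP), with the same counts adjusted over the list alone. Besides the fall of BCL2, the proapoptotic genes HRK and BCL2L11 rose by 1.99 ± 0.13 and 1.57 ± 0.09, and BMF, also proapoptotic, fell by 1.33 ± 0.10. BCL2L11 fell by 0.84 on the probe set designed for 1 gene (limma adjusted p = 0.00144) and rose by 0.93 on average, and HRK rose by 0.49 and 0.81 under these choices. On balance the list was not called (median -0.05, mean -0.02, camera direction higher, adjusted p = 0.977).

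Interferon-stimulated genes fell together. Of 25 measured, 22 fell, none rose and 3 did not pass (IFI44, IFI44L and IRF7), and adjusted over the list alone 24 fell. The median was -1.08 and camera called the list lower (adjusted p = 1.44e-08), though not with an estimated correlation (adjusted p = 0.521). Besides IFIT1 and SAMD9, XAF1 fell by 2.18 ± 0.28 and OAS3, a sensor of double-stranded RNA, by 1.93 ± 0.22. The vehicle arrays differed in these genes, with list means of 8.01, 7.66 and 7.38 in replicates 1 to 3, against 6.50 to 6.64 with GW4064. Vehicle replicate 3 had both the lowest of these means and the lowest 5' control signal. XAF1 fell by 1.14 and OAS3 by 1.02 averaged over probe sets, and among members above the median level the list median was -0.67.

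Inflammatory genes of the NF-kB pathway moved the other way. Of 23 measured, 15 rose, 1 fell (IER3) and 7 did not pass, and adjusted over the list alone 16 rose and 1 fell. The median was 0.48 (camera adjusted p = 1.38e-06, and adjusted p = 0.264 with an estimated correlation). Besides LTB, the feedback inhibitor gene TNFAIP3 rose by 1.84 ± 0.09, the cytokine gene IL32 by 1.79 ± 0.12 and the adhesion molecule gene ICAM1 by 1.75 ± 0.07. Of the 23 members 12 had a mean log2 value under 5, and of the other 11, 9 rose and 1 fell with a median of 1.345 (camera adjusted p = 0.000139). With probe sets designed for 1 gene the median was 0.31 over 16 members.

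**Figure D3:**
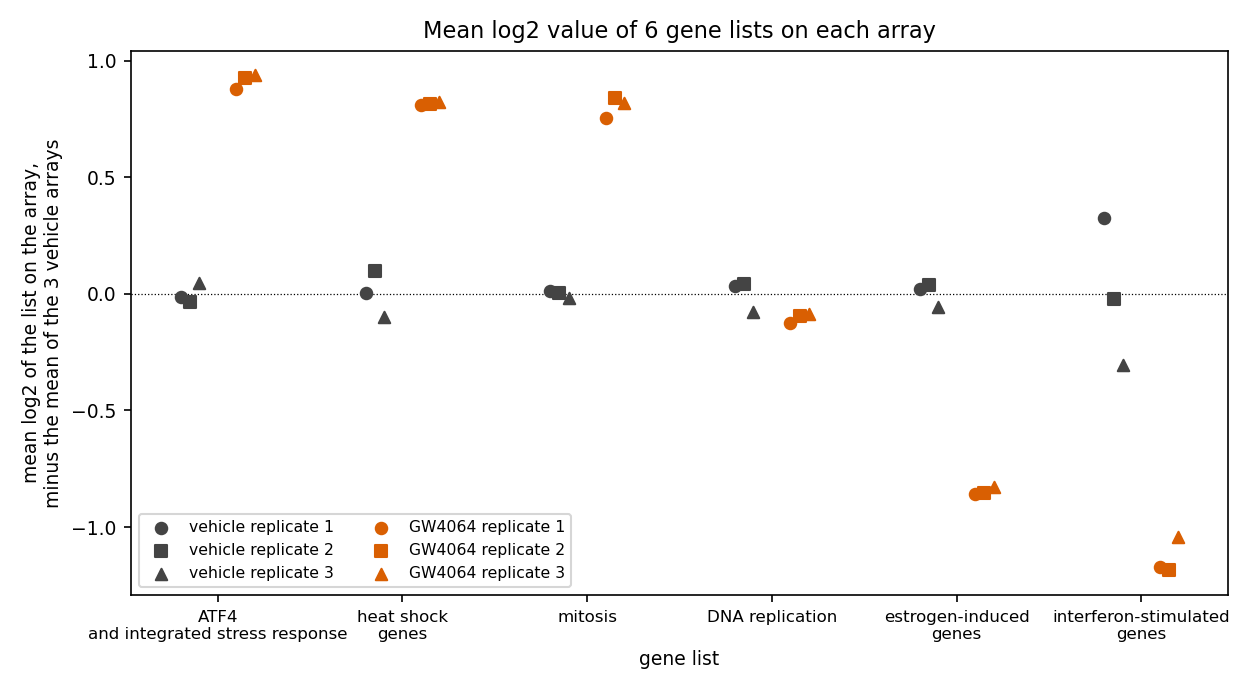
Mean log2 value of 6 gene lists (horizontal axis) on each array, less the mean of the 3 vehicle arrays (vertical axis), with symbols for the replicates. The 3 GW4064 arrays lie apart from the vehicle arrays in all 6 lists, but barely so for DNA replication (lowest vehicle array 8.317, highest GW4064 array 8.309). The vehicle arrays spread most in the interferon list (7.38 to 8.01).

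Several genes of lipid metabolism changed, while camera called none of the 3 lists of this paragraph and fry called all 3 lower (adjusted p = 0.000717 for cholesterol synthesis, 0.00296 for fatty acid synthesis and 0.00405 for LXR targets). The median turned positive with averaged probe sets for cholesterol synthesis (0.084) and fatty acid synthesis (0.00305), and for the latter also with probe sets designed for 1 gene (0.065). Of 20 cholesterol synthesis genes, 7 fell, 2 rose (HSD17B7 and MSMO1) and 11 did not pass, and adjusted over the list alone 7 fell and 3 rose (median -0.19, camera adjusted p = 0.171). Lanosterol synthase (LSS) fell by 1.91 ± 0.10, the regulator gene SREBF2 by 1.15 ± 0.10, TM7SF2 by 0.92 ± 0.07 and INSIG1 by 0.89 ± 0.08. Of 15 fatty acid synthesis genes, 8 fell, 3 rose (ELOVL5, ME1 and MID1IP1) and 4 did not pass (ACLY, LPIN1, PNPLA3 and THRSP), with the same counts adjusted over the list alone (median -0.31, camera adjusted p = 0.144). The fatty acid synthase gene FASN fell by 1.57 ± 0.10, GPAM by 0.97 ± 0.15 and the acetyl-CoA carboxylase gene ACACA by 0.87 ± 0.10. Of 12 LXR targets, 3 fell, none rose and 9 did not pass, with the same counts adjusted over the list alone (median -0.15, camera adjusted p = 0.261). The cholesterol exporter gene ABCA1 fell by 2.10 ± 0.12, the desaturase gene SCD by 0.59 ± 0.08 and SREBF1 by 0.45 ± 0.10. Averaged over probe sets, SCD rose by 0.77 (limma adjusted p = 0.00194), INSIG1 (-0.07, adjusted p = 0.756) and ACACA (-0.11, adjusted p = 0.334) did not pass, and LSS, SREBF2, FASN and ABCA1 fell by 1.01, 0.46, 0.84 and 1.02.

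Of 19 PPAR targets and fatty acid oxidation genes, 3 rose (ACADM, ECH1 and PDK4), 2 fell (CPT1A and CPT2) and 14 did not pass, with the same counts adjusted over the list alone (median 0.09, camera adjusted p = 0.66). The carnitine palmitoyltransferase genes CPT1A and CPT2 fell by 1.02 ± 0.12 and 0.58 ± 0.17, and the dehydrogenase gene ACADM rose by 0.72 ± 0.16 and ECH1 by 0.44 ± 0.07. CPT1A did not pass averaged over probe sets (-0.12, limma adjusted p = 0.488). CPT2 did not pass without vehicle replicate 1 (-0.57, adjusted p = 0.0701), GW4064 replicate 1 (-0.60, 0.0698) or GW4064 replicate 2 (-0.49, 0.0877), and fell by 0.94 on the probe set designed for 1 gene.

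Of 21 hypoxia and glycolysis genes, 7 rose, 8 fell and 6 did not pass, with the same counts adjusted over the list alone (median -0.01, camera adjusted p = 0.921). PDK1 and P4HA1 rose by 1.27 ± 0.10 and 1.03 ± 0.09, while the glycolytic genes PGAM1 and PFKFB3 fell by 0.94 ± 0.10 and 0.86 ± 0.08. Averaged over probe sets PDK1 and P4HA1 rose by 0.83 and 0.59, and P4HA1 had 0.15 with probe sets designed for 1 gene (limma adjusted p = 0.374). Of 28 oxidative phosphorylation genes, 6 rose, 3 fell (ATP5MC1, COX6C and NDUFA2) and 19 did not pass, with the same counts adjusted over the list alone (median 0.03, camera adjusted p = 0.66). UQCRC2 rose by 0.78 ± 0.17, NDUFB5 by 0.58 ± 0.19, NDUFS1 by 0.54 ± 0.07 and CYC1 by 0.43 ± 0.11. NDUFS1 rested on 1 of its 5 probe sets (average -0.07, limma adjusted p = 0.48, and -0.31, adjusted p = 0.147, on the probe set designed for 1 gene). NDUFB5 did not pass with quantile normalization repeated (0.49, limma adjusted p = 0.0613), rose by 0.35 without vehicle replicate 3 (limma adjusted p = 0.0428) and did not pass without vehicle replicate 1 (0.61, adjusted p = 0.088) or any of GW4064 replicates 1, 2 and 3 (0.604, 0.599 and 0.544, adjusted p = 0.106, 0.0921 and 0.125). CYC1 did not pass without GW4064 replicate 3 (0.41, adjusted p = 0.0546).

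Of 19 ribosome biogenesis and MYC target genes, 3 rose (HSPD1, RRP12 and RRP9), 2 fell (NOP16 and UTP20) and 14 did not pass, with the same counts adjusted over the list alone (median -0.08, camera adjusted p = 0.921). UTP20 fell by 0.76 ± 0.12 and NOP16 by 0.30 ± 0.08, and the mitochondrial chaperone gene HSPD1 rose by 0.52 ± 0.07 and RRP9 by 0.32 ± 0.08. NOP16 did not pass averaged over probe sets (-0.04, limma adjusted p = 0.693), on the probe set designed for 1 gene (-0.04, adjusted p = 0.781), or without vehicle replicate 1 or GW4064 replicate 1 or 2 (-0.30, -0.25 and -0.28, adjusted p from 0.0647 to 0.073). HSPD1 averaged over probe sets rose by 1.29, and RRP9 did not pass without GW4064 replicate 1 (0.31, adjusted p = 0.0505) or GW4064 replicate 3 (0.31, adjusted p = 0.0593). Of 20 lysosome and autophagy genes, 8 rose, 4 fell (FLCN, GLA, ULK1 and WIPI1) and 8 did not pass, with the same counts adjusted over the list alone (median 0.17, camera adjusted p = 0.557). The autophagosome membrane gene MAP1LC3B and the autophagy adaptor gene SQSTM1 rose by 1.04 ± 0.16 and 0.98 ± 0.08, while the autophagy kinase gene ULK1 fell by 1.44 ± 0.08 and the lysosomal galactosidase gene GLA by 1.27 ± 0.10. SQSTM1 rose by 1.85 on the probe set designed for 1 gene.

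Of 17 epithelial junction and keratin genes, 2 rose (CLDN3 and ESRP1), 5 fell (CDH1, GRHL2, KRT19, KRT8 and ST14) and 10 did not pass, with the same counts adjusted over the list alone (median -0.07, camera adjusted p = 0.514). GRHL2, an epithelial transcription factor gene, fell by 1.17 ± 0.07, ST14 by 0.59 ± 0.08 and KRT19 by 0.36 ± 0.07, and ESRP1 rose by 0.38 ± 0.07. KRT19 did not pass averaged over probe sets (-0.03, limma adjusted p = 0.774), where ST14 fell by 0.36 and ESRP1 rose by 0.74. Of 23 mesenchymal and invasion genes, 3 rose (PLAU, TWIST1 and ZEB2), 4 fell (CCN1, CCN2, CD44 and FN1) and 16 did not pass, with the same counts adjusted over the list alone. Its median was 0.02, its mean -0.09 and its direction in camera lower, without a call (adjusted p = 0.929). The matricellular genes CCN2 and CCN1 fell by 2.31 ± 0.19 and 1.26 ± 0.08, and the protease gene PLAU and TWIST1 rose by 1.09 ± 0.10 and 1.03 ± 0.13.

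Markers of other cell types gave no called shift. Of 4 measured basal epithelial markers, 1 fell (ITGB4, -1.08 ± 0.11) and 3 did not pass (EGFR, KRT14 and KRT5), with median 0.01, mean -0.22 and camera lower (adjusted p = 0.85). Of 10 fibroblast markers, 1 fell (COL3A1, -0.68 ± 0.14) and 9 did not pass, with median 0.06, mean -0.0029 and camera higher (adjusted p = 0.864). None of 9 leukocyte markers passed, with median -0.00096, mean 0.038 and camera higher (adjusted p = 0.786). Counts adjusted over the list alone were the same for these 3 lists. ITGB4 fell by 0.48 averaged over probe sets, and ITGB4 and COL3A1 did not pass with probe sets designed for 1 gene (-0.07 and -0.12, limma adjusted p = 0.646 and 0.49).

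Reference genes did not hold level throughout. ACTB (-0.07 ± 0.07), GAPDH (-0.01 ± 0.07), YWHAZ (0.00 ± 0.08) and TBP (0.31 ± 0.12) did not pass limma's test (adjusted p = 0.529, 0.939, 0.988 and 0.0684). TBP ranged from 0.19 to 0.41 without 1 array at a time, and passed without vehicle replicate 2 (0.41, adjusted p = 0.0119), with quantile normalization repeated (0.35, adjusted p = 0.0308) and with array weights (0.30, adjusted p = 0.00066). The last of these rests mainly on vehicle replicate 1, which held most of the weight. B2M and HPRT1 rose by 0.56 ± 0.10 and 0.47 ± 0.08, and GUSB and PPIA fell by 0.52 ± 0.09 and 0.40 ± 0.07. That made 2 rises and 2 falls among 8 measured, or 3 and 2 adjusted over the list alone, with median -0.0034, mean 0.042 and camera higher (adjusted p = 0.921). Averaged over probe sets, GUSB (-0.14, limma adjusted p = 0.136) and PPIA (-0.21, adjusted p = 0.0811) did not pass and B2M rose by 0.93. PPIA also did not pass with probe sets designed for 1 gene (-0.02, adjusted p = 0.935), where B2M rose by 1.07. With quantile normalization repeated YWHAZ had -0.09.

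The 3' minus 5' difference of the ACTB and GAPDH controls was 0.515 ± 0.373 in vehicle and 0.32 ± 0.119 with GW4064 (SD, n = 3; difference -0.195, exact two-sided permutation p = 0.7, where 0.1 is the smallest possible). Vehicle replicate 3 stood apart at 0.929, against 0.207 to 0.448 on the other 5 arrays, and without it the difference was 0.012. Among other controls, the Alu probe set fell by 0.35 ± 0.10 (limma adjusted p over all probe sets = 0.0305), and the 28S ribosomal probe sets at the 5' end and in the middle rose by 2.24 ± 0.09 and 1.77 ± 0.11.

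No list was called with the correlation estimated from the residuals of each list, by camera at adjusted p under 0.05, and 6 lists had an unadjusted p under 0.05 there. The 12 calls above were thus made by camera only in its preset setting. For the estrogen and luminal lists the estimated correlations, -0.0102 and -0.0243, lay below the preset 0.01. A higher correlation is therefore not what cost these lists their calls. By fry, 8 lists shifted higher and 11 lower, among them those of cholesterol synthesis, fatty acid synthesis, LXR, AhR, DNA replication, CDK inhibitors and epithelial junctions.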

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

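Both tests of the 28S control probe sets and the gap between list means in the interferon test were chosen after the result was seen. The tests of the mitotic genes and the other tests of the interferon genes were set once the rise and the fall were known. They were set before their own values were seen.

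The gene comparison did not use the 13522 probe sets without a single gene name. Of these, 2721 passed limma's test over all probe sets (adjusted p under 0.05), 1002 of them higher and 1719 lower with GW4064. They are noted because they carry a signal in data outside the gene comparison. They include probe sets annotated to several genes and probe sets without a gene, and single ones were not looked into beyond those that share a name with a gene of the report.

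Control probe sets for 28S ribosomal RNA, which were not part of the gene comparison, were higher with GW4064. The one at the 5' end rose by 2.24 ± 0.09, from 11.4 to 13.6 (limma adjusted p over all probe sets = 1.36e-05), and the one in the middle by 1.77 ± 0.11, from 10.3 to 12.03 (adjusted p = 5.59e-05). The one at the 3' end had 0.22 (adjusted p = 0.221). A larger share of ribosomal RNA in the labelled material would raise the 18S controls too, and their median difference was 0.122, although the 3' one of the 3 rose by 0.56 (adjusted p = 0.00287). The bacterial hybridization controls had a median difference of 0.0201 over 18 probe sets, with a range from -0.159 to 0.17. RMA brings the arrays to a common distribution and would largely remove a general difference in hybridization from these controls. Their values therefore cannot decide on that explanation. Among what stays open are a change in 28S fragments or adenylated ribosomal RNA in the treated cells and a batch that follows the groups. No test here addressed either.

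The rise of mitotic genes was set against 3 explanations. More proliferating cells at every stage would raise G1/S genes as much, but the median of the mitotic list lay 0.722 ± 0.242 (bootstrap SE) above that of a second G1/S list. The low 5' signal of vehicle replicate 3 is argued against by the median without that array, 0.819 against 0.87 with all arrays. A larger share of cells in G2 and mitosis could account for the pattern. A second list of G2/M genes, none of them in the first, had 27 rises and 2 falls among 36 and a median of 0.72. That was 0.572 ± 0.249 (bootstrap SE) above the median of the second G1/S list. Both bootstrap SEs come from resampling the genes of the lists and do not measure the spread between cultures. Cell counts per phase were not measured, so this remains a hypothesis.

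The fall of interferon-stimulated genes was larger, not smaller, without vehicle replicate 3 with its low 5' signal (median -1.19, against -1.08 with all arrays). A single vehicle culture with a high interferon state is argued against by the median without vehicle replicate 1, the highest, which was -0.876. The test of the gap between list means does not by itself settle variation between cultures. The gap between the lowest vehicle and the highest GW4064 list mean, 0.738, exceeded the range within vehicle, 0.632, by less than the SD of the vehicle list means, 0.317. The genes also vary together, with an estimated inter-gene correlation of 0.635, the highest of the 34 lists. Tests that use the spread between cultures argue against such variation as the whole account of this list. In limma's test 22 of 25 genes fell and none rose, and fry called the list lower (adjusted p = 0.00698). Because the genes vary together, the 22 falls are not independent results. Camera, which compares the list with other genes, did not call it with the estimated correlation (adjusted p = 0.521). The list mean differed by -1.13, with an SD of 0.317 in vehicle and 0.0788 with GW4064 (n = 3 per group). A batch that follows the groups could not be examined.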

How the results depend on the processing

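All alternatives were planned, and none was added after the values were seen. Without 1 array at a time the counts ranged from 2502 to 3765 genes higher, 3408 to 4352 lower, 461 to 673 at least 2-fold higher and 872 to 1009 at least 2-fold lower, and 5 to 7 lists were shifted higher and 5 lower. Both filters on dim genes, median centring, repeated quantile normalization and the trended robust variance kept these counts within 1.5 times. With a replicate block 2821 genes were higher and 3673 lower, but arrays of the same number did not correlate (r = -0.207, -0.346 and -0.201), so the numbers give no pairs. The average of a gene's probe sets left 440 genes at least 2-fold higher and 437 at least 2-fold lower. Of 6009 genes called under both choices 192 had the opposite direction. With probe sets designed for 1 gene these were 204 of 5506. Array weights gave 7659 genes higher, where the weights stopped before tolerance and put 54.96 on vehicle replicate 1, so that this count rests on 1 array. Tested singly, which tests more features, 7557 probe sets were higher, 8766 lower, 2017 at least 2-fold higher and 2406 at least 2-fold lower. Camera with an estimated correlation called 0 lists higher and 0 lower (6 at unadjusted p under 0.05), and fry called 11 lower.

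Signs that reversed, for which the cause was not tested, were these. With a mean log2 of at least 5, medians were -0.00445 for FXR-induced, -0.0416 for mesenchymal and -0.117 for basal genes. Among genes above the median level, they were 0.000396 for hypoxia and -0.315 for mesenchymal genes. With the average of probe sets, PRLR had 0.549, MYB 0.020, SCD 0.765, NDUFS1 -0.0654, CYP19A1 -0.0237 and ERBB2 0.117. List medians there were 0.0844 for cholesterol synthesis, 0.00305 for fatty acid synthesis, 0.0273 for PXR and CAR targets, 0.105 for the BCL2 family, 0.0217 for hypoxia, 0.0254 for ribosome biogenesis, 0.0459 for leukocyte and 0.0555 for reference genes. With probe sets designed for 1 gene, SLC27A5 had -0.00697, BCL2L11 -0.837, FGFR2 0.0866 and NDUFS1 -0.306. List medians there were -0.00697 for FXR-induced genes, 0.0654 for fatty acid synthesis, -0.231 for AhR targets, -0.0304 for metallothioneins, -0.033 for lysosome, -0.031 for mesenchymal and 0.173 for reference genes. With quantile normalization repeated, CYP19A1 had -0.00302, YWHAZ -0.0948 and the oxidative phosphorylation median was -0.0241. With array weights, FGF19 had 0.00411, GAPDH 0.00742 and medians were 0.0208 for hypoxia, 0.0518 for leukocyte and 0.0272 for reference genes.

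Without 1 array at a time, signs changed within -0.0339 to 0.0594 for NR0B2, -0.0183 to 0.0762 for CYP19A1, -0.0259 to 0.0538 for YWHAZ, -0.0996 to 0.0161 for FGF19 and -0.0231 to 0.0129 for GAPDH. List medians did so within -0.0324 to 0.121 for mesenchymal, -0.0869 to 0.0982 for basal, -0.00416 to 0.038 for leukocyte and -0.0224 to 0.0334 for reference genes. For PXR and CAR targets the range was -0.168 to 0.0408, for the BCL2 family -0.0808 to 0.0453 and for CDK inhibitors -0.000915 to 0.116. The RNA quality difference ranged from -0.349 to 0.012 (without vehicle replicate 3). Of the other values of named genes under alternatives that kept all arrays, 1262 kept direction and side of the threshold, 27 lost the call and 4 gained one, and without 1 array 889 kept both, 17 lost the call and 1 gained one. For lists, 320 kept both, 17 lost the call and 7 gained one, and without 1 array 187 kept both and 2 lost the call. Background limits the fold of dim genes such as SLC51A.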

Other observations

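The 4 gene groups of this paragraph and the next were chosen after their values were seen, while the counts over other splits of the arrays were planned. Of 16 measured genes of the circadian clock (19 in the group), 7 were higher, 5 lower and 4 did not pass limma's test, with a median of 0.10, and no list test was run on any of the 4 groups. The transcription factor genes HLF, RORA, NFIL3 and DBP rose by 2.38 ± 0.20, 1.61 ± 0.16, 1.41 ± 0.19 and 1.35 ± 0.08, and the repressor genes CIART and CRY1 by 2.05 ± 0.12 and 1.16 ± 0.09. The activator gene BMAL1 rose by 0.46 ± 0.08, while NPAS2 fell by 0.85 ± 0.08, TEF by 0.69 ± 0.08 and CLOCK by 0.46 ± 0.08. BHLHE41 fell by 0.43 ± 0.09 and CRY2 by 0.31 ± 0.10, and TEF had this direction on 1 of its 4 probe sets and BHLHE41 on 2 of 4. Limma's adjusted p was at most 0.0361 for these genes.

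Of 12 genes of PI3-kinase and AKT 8 were measured, and 6 of these were lower. Beside PIK3R3, the regulatory subunit gene PIK3R1 fell by 2.19 ± 0.08, PIK3C2B by 1.29 ± 0.09, AKT1 by 0.71 ± 0.12, AKT2 by 0.62 ± 0.09 and PIK3CB by 0.31 ± 0.08, where AKT2 had this direction on 4 of 7 probe sets and PIK3CB on 1 of 2. The phosphatase gene INPP4B (1.11 ± 0.08, on 1 of 4 probe sets) and the inhibitor gene PIK3IP1 (0.33 ± 0.08) rose. All 6 histone methyltransferase genes of the KMT2 and SETD1 families were lower on the probe set used. KMT2D fell by 1.93 ± 0.12 (a direction on 4 of 6 probe sets), SETD1B by 1.37 ± 0.08 and KMT2A by 1.28 ± 0.10 (on 2 of 11 probe sets). KMT2B, KMT2C and SETD1A fell by 0.62 ± 0.12, 0.54 ± 0.12 and 0.53 ± 0.09. Of 46 histone genes 25 were higher and 5 lower (H1-6, H2BC4, H2BC5, H2BC12 and H3C6), with a median of 0.36. H1-4 rose by 1.83 ± 0.12, H3C7 by 1.79 ± 0.14 and H4C11 by 1.71 ± 0.10. Histone genes are near-identical copies, so that single members are uncertain. Some of the rises lay near the bottom of the scale, such as those of H1-5 (3.32 in vehicle, 3.65 with GW4064) and H4C13 (3.71 and 4.16). Limma's adjusted p was at most 0.0117 for the PI3-kinase and methyltransferase genes.

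Probe sets of 1 gene often disagreed. Of 10523 genes with more than 1 probe set, 6178 had at least 1 that passed, and 1079 of these had both a rise and a fall that passed. The direction given for genes such as PDCD4, BCL2, ESR1, ERBB2, RXRA and KMT2A is therefore that of the probe set used. Whether transcript ends or weak probe sets lie behind this was not tested.

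The 6 arrays can be split into 3 and 3 in 10 ways. The real split gave 7618 genes past limma's threshold, 1476 of them with at least a 2-fold difference, and 12 lists past camera's, and 1 split of the 10, the real one, reached each of these. The highest count of any other split was 0 genes, 0 genes with a 2-fold difference and 10 lists. With 10 splits, a share under 0.05 is out of reach. Each other split put arrays of both groups on both sides. Part of the treatment difference thus stayed in its contrast, and part entered the spread within its sides. Neither the 0 genes nor the up to 10 lists are counts without a treatment difference. These splits therefore cannot show how strong or weak a call by camera is.

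The control probe sets for STAT1 did not pass limma's test. The 3' one had -0.16 ± 0.15 (limma adjusted p over all probe sets = 0.482), and the 5' one and the 2 middle ones had 0.97 ± 0.49, 0.52 ± 0.40 and 0.92 ± 0.63 with adjusted p of at least 0.195. The SD of the 5' and middle ones was 0.881 to 1.44 in vehicle, against 0.215 to 0.351 with GW4064. Vehicle replicate 3 had the lowest 5' signal of the ACTB and GAPDH controls, so the 5' and middle ones say little about STAT1. The 3' one varied less, with an SD of 0.302 in vehicle and 0.0543 with GW4064.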
